A study of Homo sapiens with 4 samples.

How the data were processed

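Gene expression was measured in 4 cultures of cutaneous T-cell lymphoma lines (parental and vorinostat-resistant MyLa, parental and vorinostat-resistant MJ) after 48 hours, with 1 sample per group. Total RNA labelled with Cy3 was hybridised to Agilent human gene expression arrays, and per the file headers all 4 lie on 1 slide read in 1 scan with Feature Extraction 11.0.1.1, so no batch could be tested. The authors deposited 1 scanner file per array, whose processed signal is an intensity from which the software had subtracted background and which is not normalized between arrays. Raw median spot and local background brightness, also as intensity, are in the same deposited files. The authors also deposited a table of 1 value per probe and array on the log2 scale, with no statement of how it was made. Its columns have medians of 0.0788 (parental MyLa), -0.0381 (resistant MyLa), 0.0418 (parental MJ) and -0.327 (resistant MJ), and each probe's median over the 4 arrays is 0. Differences between its columns equal those of log2 processed signal minus each array's 75th percentile (correlations of at least 0.999997, median offsets of at most 0.0012), so its scale, centring and direction are settled and it served as an alternative. No column of values per sample was left unused.

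Each array holds 62976 spots, of which 60901 are not controls and carry 58201 distinct probes, 300 of them printed on 10 spots each. Spots the software marked as non-uniform or as population outliers (61 to 114 per array) were left out, which lost 2 probes, and repeated spots were combined by the mean of their log2 signals. The fixed plan named leaving those spots out as the alternative, so the choice and its alternative, all spots kept, were exchanged here, and both are reported. No spot was saturated. A probe's value was log2 of the processed signal minus the 75th percentile of all probes on its array, which was 124.6, 158.8, 151.1 and 208.4 for parental MyLa, resistant MyLa, parental MJ and resistant MJ. Probes were named by the RefSeq accession of the array's design file looked up in the reference annotation. Of the probes, 31769 carry such an accession and 31103 could be named, while 27096 were left unnamed, among them 9747 designed to Ensembl transcripts. The array was designed on another genome build (hg19) than the annotation (GRCh38), so genes are given by symbol and chromosome and no coordinates are printed. A gene was represented by its probe with the highest mean over the 4 arrays, which gave 22374 genes, 12179 of them well above background on all 4 arrays. Genes of the Y chromosome and of X inactivation were left out.

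A gene well above background on both arrays compared has a measured difference. A gene well above background on 1 array has a bound, with the dim side set to the higher of its own signal and that array's lowest signal well above background (9.15 to 10.3), and bounds were counted apart. With 1 array per group there is no test within a line, so genes were counted at a difference of at least 2-fold. The spread between spots of a probe gives a difference a 95% interval of 0.14 log2 units in MyLa and 0.13 in MJ, which covers spot error alone and not variation between cultures. Of the genes counted in MyLa, 514 had several probes and 39 of these had probes of both signs, and in MJ 15 of 241 did. Genes past 2-fold in both lines were counted against the product of the list sizes divided by the number of genes. The change shared by the lines was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p of 0.05) on genes well above background on at least 2 of the 4 arrays, with the line as a block pairing each resistant array with its parent. On simulated data with the spread of these arrays, limma passed 0 of 50 genes changed by log2 1, 2, 4 or 6, with the right sign for 47, 50, 50 and 50 and with 0 false calls. With the spread divided by 10 it passed 46, 50, 50 and 50, with 11 false calls.

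Gene lists, 42 in number plus 8 lists of markers of other cell types, were ranked by the median difference of their measured members among 10000 random lists of the same size matched on mean expression in 20 bins, drawn with a fixed seed. A list under percentile 2.5 is called lower and 1 over percentile 97.5 higher, and lists with fewer than 5 measured members were not ranked. This describes these arrays and gives no p. On simulated data, 7 of 200 random lists and 50 of 50 shifted lists were called, and 200 of 200 changed genes were counted. The noise in that simulation was far smaller than the spread of the measured differences (SD 0.96 in MyLa). Its changed genes were set to differ by more than 2-fold, so these counts do not give the sensitivity on these arrays. Genes were named by rule: per line, the 12 largest measured rises and falls and the 6 largest bounds per direction, the 10 genes per direction with the largest smaller change in both lines, the 5 per orientation with opposite changes, the 5 largest per direction between the parental lines, up to 4 members per list and line, and a fixed set of genes around the drug's targets. The comparisons, lists, thresholds, naming rule and alternatives were fixed before the data were examined, save where a later choice is named as such.

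The alternatives were quantile normalization, scaling on the median of probes well above background on all arrays, normexp background correction (offset 50), the deposited value table, only genes well above background on all 4 arrays, no filter on dim genes, the mean over a gene's probes, thresholds of 1.5-fold and 3-fold, all spots kept, and for limma no replicate block, each array left out, an eBayes trend and an adjusted p of 0.10. For lists they were the mean of the members, only members well above background on both arrays, and random lists not matched on expression. An alternative chosen after seeing the data scaled each array on the 75th percentile of the probes well above background on all 4 arrays, since 43.0% to 46.9% of the probes were well above background. The files hold no mean spot signal, so normexp was run on the median spot signal, also a choice made after seeing the data. Neighbouring genes were examined on the autosomes in windows of 40 measured genes, against 1000 permuted gene orders. Other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Some single genes are not reported here.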

Results

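RNA from 2 human cutaneous T-cell lymphoma lines, MyLa and MJ, was compared with RNA from a derivative of each line that had been grown in rising amounts of vorinostat, an inhibitor of histone deacetylases (HDACs), until it was resistant. Each of the 4 cultures had been kept for 48 hours and was hybridised to 1 array, so each group holds 1 sample and no difference within a line has a replicate behind it. The labels do not say whether vorinostat was present during those 48 hours. Of 58199 probes, 43.0% were well above background in parental MyLa, 44.7% in resistant MyLa, 44.1% in parental MJ and 46.9% in resistant MJ. The precision is limited by the single array per group, and spots of the same probe on 1 array differed by a median SD of 0.0447 to 0.0564 log2 units. Differences are given as resistant minus parental on the log2 scale, and a gene is said to have risen or fallen where it differed by at least 2-fold. Where a gene was well above background on only 1 of the arrays compared, its fold is a lower bound and is written as "at least". Some large measured folds rest on a signal near the lowest counted as well above background (9.15 to 10.3), so their size is imprecise. Among such signals were 13.3 for IFNG, 14.3 for CA2 and 18.1 for SPP1 in parental MJ, and 16.8 for LAPTM4B in resistant MJ. In resistant MyLa they included 20.9 for CD3D, 14.2 for OSBPL10 and 14.3 for FABP6, and other genes named below had signals as low.

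The comparison within MyLa asks which transcripts differ between cells that resist vorinostat and the cells they came from. Resistant MyLa carried far more transcript of IFNG, which encodes interferon gamma, and more of some genes that interferons induce. It carried less of 5 of the 7 measured metallothioneins and far less of the T cell receptor subunit CD3D and of the cytokine IL17F. Across the array, 1147 genes rose and 1058 fell among 12870 genes measured on both MyLa arrays, and another 300 rose and 334 fell by a bound of at least 2-fold. The median difference of all measured genes was 0.05, and 63.5% of them lay within 1.5-fold.

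Osteopontin, a secreted glycoprotein encoded by SPP1, had the largest measured rise in MyLa at 508-fold (log2 8.99). It was followed by UBD, a ubiquitin-like modifier that interferon gamma and tumour necrosis factor induce (8.38), ARHGEF10, a guanine nucleotide exchange factor (8.31), and FRG2C (7.41) with its paralog FRG2 (7.08). The chemokine gene CXCL9, a target of interferon gamma, was higher by 7.34, the guanylate-binding protein gene GBP4 by 7.20 and IFNG by 6.82, which is 113-fold. DDX4, an RNA helicase of germ cells, was higher by 6.51, and DHRS2, a short-chain dehydrogenase gene that HDAC inhibitors commonly induce, by 6.46. The pseudogene WFDC21P was higher by 7.38. SPOCK2, a proteoglycan gene, was higher by 7.19 on its brighter probe but by -0.18 on another. Genes dim in parental MyLa and bright in resistant MyLa included the pluripotency factor SOX2 (at least 454-fold), the GTPase-activating protein ARHGAP44 (at least 434-fold), the phospholipid flippase ATP8A2 (at least 236-fold), the mitophagy receptor BNIP3 (at least 233-fold), autotaxin, encoded by ENPP2 (at least 168-fold), and the phosphatase PTPRR (at least 166-fold).

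Among the falls in MyLa, IL17F was 610-fold lower (log2 -9.25) and CD3D 572-fold lower (-9.16), while CD3E was not well above background on either MyLa array. OSBPL10, an oxysterol-binding protein gene, was lower by -8.86, the transcription factor gene ONECUT2 by -7.27 and ADIRF by -7.26. EDN2, which encodes endothelin-2, was lower by -6.99, the collagen gene COL15A1 by -6.70, the kinase gene ALPK3 by -6.69 and ANKRD35 by -6.63. IFI30, an interferon gamma-inducible thiol reductase of the lysosome used in antigen processing, was lower by -6.14. Transcripts that were bright in parental MyLa and dim in resistant MyLa were led by RAMP1, the partner of the calcitonin receptor-like receptor (at least 2354-fold lower), and CASP4, an inflammatory caspase (at least 1411-fold lower). They were followed by the lipid transporter ABCA12 (at least 1079-fold), the NK cell receptor KIR2DS2 (at least 993-fold), WDFY4 (at least 629-fold) and the G protein regulator RGS12 (at least 577-fold).

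In resistant MyLa, 10 of 20 measured interferon-stimulated genes rose, 1 fell and 14 lay above 0, with a median of 1.05, at percentile 100 among 10000 random lists matched on expression. IFI35 was higher by 3.53, USP18, which limits interferon signalling, by 3.50, IFIT1 by 3.17 and RSAD2 by at least 76.3-fold. Of 16 genes of MHC class I presentation, which shows peptides to cytotoxic T cells, 4 rose and 0 fell, with a median of 0.74 (percentile 100). Its members included the immunoproteasome subunit PSMB9 (1.38), HLA-F (1.21) and B2M (1.17). Of 20 targets of p53, 7 rose and 1 fell, with a median of 0.76 (percentile 100). TP53INP1 was higher by 3.23, RRM2B by 2.17, FAS by 1.54 and MDM2 by 1.39, while CDKN1A, the best known target, stood at 0.13. TP53INP1 and RRM2B lie on chromosome 8, whose genes were shifted upward as a group in MyLa (median 0.63), and the list without them had a median of 0.66. Among 18 genes of autophagy and the lysosome, 4 rose, HEXA (1.41) and CTSD (1.25) among them, and 0 fell. Their median of 0.37 (percentile 97.7) was no longer called with quantile normalization, with random lists not matched on expression or with the list's mean.

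Metallothioneins, which bind zinc and copper, showed the largest list shift in MyLa, where 5 of 7 measured members fell and 0 rose, with a median of -5.44 (percentile 0). Probes of similar members may read 1 transcript, so this count and percentile may rest on fewer separate signals. MT1L was lower by -5.86, MT1B by -5.69, MT2A by -5.46 and MT1E by -5.44. The 20 measured genes of cholesterol synthesis included 4 that fell, such as INSIG1 (-1.92), MVD (-1.37) and SREBF2 (-1.07), and 0 that rose, with a median of -0.48 (percentile 0.08). With normexp background correction MVD (-0.91) and SREBF2 (-0.97) were under 2-fold. Of 24 targets of NF-kB, 7 fell and 3 rose, with a median of -0.41 (percentile 0.05). CCL17, a chemokine for skin-homing T cells, was lower by -3.36, CCL5 by -2.54, LTA by -2.29 and NFKB1 by -1.54, while TNFAIP3, an inhibitor of the pathway, was higher by 2.31.

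Further lists were lower in resistant MyLa, but their calls ended under some alternatives. Glycolysis and hypoxia genes had 7 of 26 members that fell, such as PFKFB4 (-2.37), PFKL (-1.77) and the glucose transporter SLC2A3 (-1.65), and 3 that rose. Their median was -0.38 (percentile 0.06) and their mean of -0.16 was not called. Fatty acid metabolism, with 3 of 20 members that fell and 2 that rose, had a median of -0.43 (percentile 0.10), and its mean was not called. The fatty acid receptor CD36 was higher by 6.46 (88.0-fold) against that median, and ACSL3 was lower by -1.58. Of 24 cytokine and chemokine genes, 9 fell and 6 rose, with a median of -0.37 (percentile 0.47). IL22 was at least 158-fold higher, IL5 was higher by 4.07 and CCL3 was lower by -3.48. Cytotoxic effector genes had a median of -1.01 (percentile 0.34) over 9 members, of which 5 fell and 2 rose. The pore-forming protein gene PRF1 was at least 19.5-fold lower, the granzyme GZMM was lower by -2.28, and the receptor KLRD1 was at least 18.7-fold higher. NRF2 targets and thioredoxin and glutathione genes had a median of -0.24 (percentile 2.37) over 20 members, of which 2 fell and 1, the aldo-keto reductase AKR1C3, rose by at least 65.3-fold. T cell fate transcription factors were called higher, with a median of 0.53 (percentile 99.9), 6 of 23 members that rose, such as ZEB1 (1.59), IKZF3 (1.55) and GATA3 (1.51), and 5 that fell, such as ID2 (-1.88). That call, like the cytokine and cytotoxic ones, ended without the filter on dim genes and with the list's mean, and the call on NRF2 targets ended with the deposited value table (percentile 2.62), with the mean and with unmatched random lists. With only genes well above background on all 4 arrays, the fate factor (0.020) and cytotoxic (-0.66) calls ended.

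The comparison within MJ asks the same question in the other line. Resistant MJ also carried far more IFNG transcript, 116-fold more than parental MJ (log2 6.86), and more of several interferon-stimulated genes. It carried less of the transcription factor MAF, of the inflammatory caspases CASP4 and CASP5 and of CCL17. In MJ, 691 genes rose and 591 fell among 13546 measured on both arrays, and 276 rose and 145 fell by a bound of at least 2-fold. The median difference was -0.07, and 77.5% of genes lay within 1.5-fold.

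Carbonic anhydrase II, encoded by CA2, had the largest measured rise in MJ at 123-fold (log2 6.95). NIPAL4 was higher by 5.90, TEX19, a gene of germ cells, by 5.15, STEAP1B by 4.93, glutamine synthetase, encoded by GLUL, by 4.92 and the cytokine gene IL26 by 4.87. NETO2 was higher by 4.78, the choline transporter SLC44A1 by 4.74, the phosphatase PTPRU by 4.72 and AUTS2 by 4.71. AUTS2 had another probe at -0.37, and the probes of MBP, which encodes myelin basic protein, went both ways, at 4.83 and -3.56. Genes dim in parental MJ included the chemokine receptor CCR2 (at least 142-fold higher in resistant MJ), P-cadherin, encoded by CDH3 (at least 90.1-fold), the kinase DYRK2 (at least 89.8-fold), HS3ST4 (at least 85.8-fold), CCBE1 (at least 53.4-fold) and PARP9 (at least 46.4-fold).

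The lysosomal membrane protein gene LAPTM4B had the largest measured fall in MJ at 635-fold (log2 -9.31). MAF was lower by -6.79, CASP4 by -6.09, CCL17 by -6.06 (66.9-fold), the synaptotagmin SYT4 by -6.03 and CASP5 by -5.52. SAMSN1, an adaptor protein gene, was lower by -5.47, the proton-sensing receptor GPR65 by -5.40, ACOT12 by -5.01, IL17B by -4.93, STOX2 by -4.85 and FABP6, a bile acid-binding protein gene, by -4.83. Transcripts bright in parental MJ and dim in resistant MJ were MLC1 (at least 365-fold lower), the microsomal glutathione transferase MGST1 (at least 219-fold), TMT1A (at least 107-fold), the adhesion receptor ADGRL2 (at least 89.5-fold), butyrylcholinesterase, encoded by BCHE (at least 41.3-fold), and the calcium channel RYR2 (at least 32.4-fold).

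In resistant MJ, 10 of 25 measured interferon-stimulated genes rose and 3 fell, with a median of 0.83 (percentile 100). EPSTI1 was higher by 2.39, IRF7 by 1.49 and ISG20 by 1.41, while IFI44 was lower by -3.59. Genes commonly induced by HDAC inhibitors had a median of 0.56 (percentile 99.98), with 5 of 15 members that rose and 2 that fell. DHRS2 was higher by 3.05, KLF2 by 2.32, TXNIP, a thioredoxin-binding protein gene, by 1.98 and GADD45B by 1.22. Of 24 genes of the ATF4 and unfolded protein responses, which answer to amino acid shortage and misfolded protein, 6 rose and 0 fell, with a median of 0.27 (percentile 100). They included CTH (2.39), DDIT3 (1.98), CHAC1 (1.97) and CEBPB (1.76). The JAK-STAT and IL-2 family list had a median of 0.18 (percentile 99.9), with 4 of 24 members that rose, SOCS2 (1.66) among them, and 1 that fell, SOCS1 (-1.19). The median of 29 proliferation genes was 0.20 (percentile 100), with 0 that rose or fell, and 15 of the 29 lay above 0.

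Genes of MHC class II presentation were lower in resistant MJ, with a median of -0.58 (percentile 0.01) over 14 members, of which 2 fell, HLA-DQA1 (-1.18) and HLA-DMA (-1.07, and -0.97 on another probe), and 0 rose. With normexp background correction HLA-DMA stood at -0.99. Cholesterol synthesis genes had a median of -0.36 (percentile 0.30), with 18 of 20 below 0 and 0 that fell by 2-fold. Cytotoxic effector genes had a median of -0.96 (percentile 0.02) over 11 members, of which 5 fell, such as cathepsin W, encoded by CTSW (-3.75), and granzyme B, encoded by GZMB (-2.94), and 0 rose. Of 25 cytokine and chemokine genes, 7 fell and 5 rose, with a median of -0.31 (percentile 0.45). IL6 was lower by -4.57, XCL1 by -3.74 and CSF2 by -3.31, and IL4 was higher by 1.77. T cell receptor genes had a median of -0.29 (percentile 1.40), with 4 of 18 that fell, CD3D (-4.04), the kinases ZAP70 (-1.64) and LCK (-1.22), and the phosphatase PTPRC (-1.60), and 1 that rose, FYN (1.21). The median of 9 inhibitory receptor and exhaustion genes was -0.59 (percentile 0.24), with 0 that rose or fell. Drug conjugation enzymes had a median of -0.51 (percentile 0.71), with 4 of 10 that fell, MGST1 and GSTA4 (-1.28) among them, and 1 that rose.

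T cell fate transcription factors were called higher in MJ, with a median of 0.19 (percentile 99.5), 5 of 26 members that rose, such as TBX21, the master regulator of Th1 cells (4.58), and 2 that fell, MAF and RUNX1 (-3.33). The NF-kB target list was called higher as well (median 0.12, percentile 99.5), but only IRF1 (1.39) rose while 4 of 24 members fell, CCL17, CCL5 (-1.68), TNFAIP2 (-1.32) and REL (-1.06). Its mean was -0.30, of the other sign, and it was not called against unmatched random lists. Glycolysis and hypoxia genes had a median of -0.32 (percentile 1.22), with 3 of 24 that fell, SLC2A3 (-1.80) and PFKFB4 (-1.35) among them, and 1 that rose, PFKFB3 (1.68). SLC2A3 stood at -0.85 with normexp background correction. The control list of 28 ribosomal protein genes had a median of -0.39 (percentile 0.81), which became -0.023 with quantile normalization and was no longer called. The T cell receptor call ended with quantile normalization (-0.18) and with normexp background correction (-0.17), and the fate factor, cytokine, cytotoxic and glycolysis calls ended with only genes well above background on all 4 arrays. Without the filter on dim genes, the drug conjugation and inhibitory receptor calls ended, and the inhibitory receptor, fate factor and glycolysis lists were not called by their mean.

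**Figure D1:**
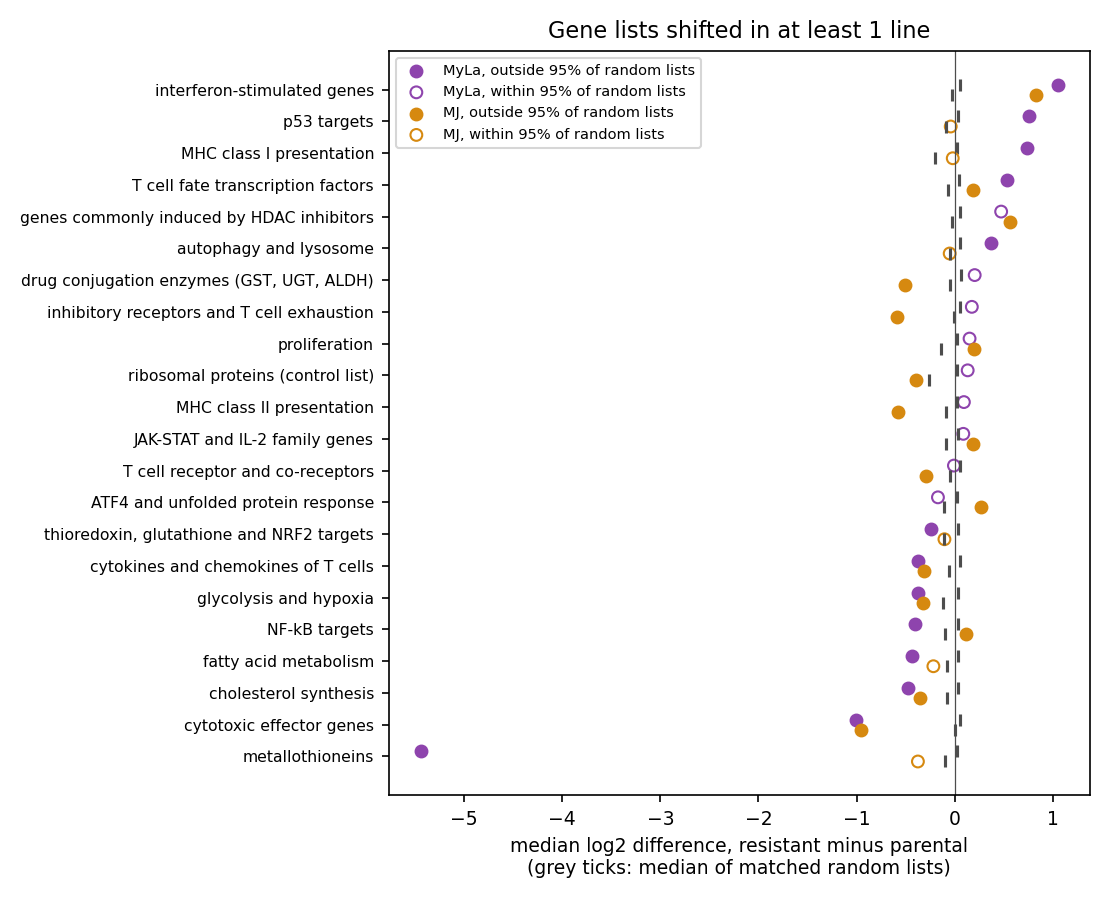
Median log2 difference, resistant minus parental, of the 22 gene lists called in at least 1 line (x axis) for MyLa (purple) and MJ (orange). Filled circles lie outside the central 95% of 10000 matched random lists, open circles lie within it and grey ticks mark the random lists' median. The metallothioneins in MyLa lie at -5.44, and the interferon-stimulated genes lie at 1.05 in MyLa and 0.83 in MJ.

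Several lists called in 1 line were not called in the other, and the difference between the lines was not tested, since each line gives 1 value. In MyLa, genes commonly induced by HDAC inhibitors had a median of 0.47 (percentile 97.3), with DHRS2, GADD45B (3.05) and TXNIP among 4 of 13 that rose and with 1 that fell, and the list was called higher there with quantile normalization and with the mean over a gene's probes. The other medians in MyLa were 0.20 for drug conjugation enzymes, 0.17 for inhibitory receptors, 0.15 for proliferation, 0.13 for ribosomal proteins, 0.09 for JAK-STAT and IL-2 family genes, 0.09 for MHC class II, -0.01 for T cell receptor genes and -0.17 for the ATF4 and unfolded protein responses. Of the 18 T cell receptor genes 6 fell and 2 rose in MyLa, and by its mean (-0.995) that list was called lower, as was the ATF4 list by its mean (-0.36) and without the filter on dim genes. In MJ the medians were -0.02 for MHC class I presentation (percentile 97.4), -0.04 for p53 targets, -0.05 for autophagy and lysosome, -0.10 for NRF2 targets, -0.22 for fatty acid metabolism and -0.38 for metallothioneins (percentile 3.12). MHC class I presentation was called higher in MJ under 5 alternatives and the metallothioneins lower under 2.

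The lists of histone deacetylases, the drug's own targets, of genes for and against apoptosis, of death receptor genes and of drug efflux transporters were not called in either line, although single members changed. Of the histone deacetylases, 1 of 10 measured in MyLa rose, HDAC5 (1.80), and 0 of 11 in MJ, with list medians of -0.20 and 0.15. The brighter probe of HDAC6 stood at -0.27 in MyLa and 0.22 in MJ, but its other probe gave -1.47 and -0.91. HDAC1 stood at -0.40 in MyLa and -0.39 in MJ, and HDAC3 at 0.32 and -0.61. Anti-apoptotic BCL2 and IAP genes had medians of -0.11 and -0.03, with BCL2 at -0.18 in MyLa and 0.62 in MJ and with BIRC3 (-1.75 in MyLa) the only member that fell. Pro-apoptotic BCL2 family genes had medians of 0.29 and 0.05. In MyLa 1 of 11 rose, BNIP3, and the list was called higher by its mean (0.82), while in MJ 3 of 12 rose, such as PMAIP1 (1.29), and 1 fell. Death receptor genes had medians of 0.31 and 0.00, with 3 of 11 that rose in MyLa, FAS among them, 2 of 11 in MJ and 0 that fell. That list was called higher in MyLa with only genes well above background on all 4 arrays (0.53) and in MJ by its mean (0.37). ABC multidrug transporters had medians of -0.27 and 0.09. In MyLa 3 of 8 fell, ABCA3 (-1.66), ABCC6 (-1.30, with another probe at -0.40) and ABCC4 (-1.01), and 0 rose, and with normexp background correction ABCC6 (-0.76) and ABCC4 (-0.71) were under 2-fold. In MJ 1 of 10 rose and 1 fell. ABCB1, the P-glycoprotein gene, was not well above background on either MyLa array and stood at 0.50 in MJ, and ABCC1 was lower by -1.09 in MJ (-0.97 with normexp background correction).

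The remaining lists were called in neither line, though some were under an alternative, and their medians are given for MyLa and then MJ. Chromatin lists gave 0.25 and 0.14 for sirtuins, -0.18 and 0.09 for histone acetyltransferases and bromodomain readers, -0.03 and -0.01 for polycomb and DNA methylation, and -0.28 and 0.11 for linker and core histones. Growth and repair lists gave 0.26 and 0.14 for G1 cyclins and CDK inhibitors, 0.01 and -0.12 for DNA repair, 0.08 and -0.08 for PI3K-AKT-mTOR genes, 0.32 and -0.23 for MAPK feedback targets, and 0.20 and 0.26 for NOTCH, WNT and TGF-beta targets. Members with large changes were the double-strand break kinase ATM (-2.50 in MyLa), FOXO3 (2.31 in MyLa), the mTOR inhibitor DEPTOR (2.73 and 2.43), the phosphatase DUSP6 (4.58 in MyLa) and PIK3CG (-4.72 in MJ). Chemokine receptors and skin homing gave -0.17 and 0.00, with CXCR4 higher in both lines (1.60 and 1.90), CCR6 lower in both (-3.36 and -1.58) and CCR4 lower by -2.13 in MJ. Cutaneous T-cell lymphoma marker genes gave -0.15 and 0.06, with STAT4 lower by -3.92 in MyLa and MYBL1 higher by 2.49 there. Heat shock proteins gave 0.11 and -0.09, cancer-testis antigens -0.36 and 0.00, adhesion and cytoskeleton genes -0.17 and -0.12, and the control list of housekeeping genes -0.15 and -0.17.

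Marker lists of other cell types were mostly near or under background, with 2 to 6 members measured per list and line. The NK cell markers were called lower in MyLa (median -1.44, percentile 2.02), where KIR3DL1 was at least 353-fold lower and KIR2DL4 at least 287-fold lower, while KLRD1 and KLRF1 (at least 8.42-fold) were higher. That call ended with normexp background correction, without the filter on dim genes and with the mean over a gene's probes. In MJ the NK cell median was -1.55 over 4 members, too few to rank. The other marker medians, for MyLa and then MJ, were -0.44 and -0.32 for B cells, 1.29 and -0.21 for monocytes or macrophages, -0.22 and 0.35 for erythroid cells, 0.56 and -0.09 for keratinocytes, -0.10 and 0.12 for fibroblasts, 0.17 and 0.12 for endothelial cells, and -0.75 and -0.01 for epithelial cells, and none of those ranked was called.

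What the resistant derivatives of both lines shared was asked next. IFNG was higher by more than 100-fold in both, and the ubiquitin ligase gene NEURL3 (5.16 in MyLa and 4.58 in MJ), SPP1 (8.99 and 3.17), DHRS2 (6.46 and 3.05), TEX19 (2.90 and 5.15) and GBP4 (7.20 and 2.37) rose in both. FBXO32, a ubiquitin ligase gene of protein breakdown (2.91 and 2.65), RBKS, which encodes ribokinase (2.44 and 2.82), DEPTOR and LRRC8C, a subunit of volume-regulated anion channels (2.28 and 2.58), also rose in both. FABP6 (-4.80 and -4.83), CD3D (-9.16 and -4.04), CCL17 (-3.36 and -6.06), ZG16B (-4.96 and -3.38), the chemokine CCL3L3 (-3.64 and -2.70), IL1RN, the interleukin-1 receptor antagonist gene (-3.27 and -2.72, but -0.29 and -0.64 on another probe), and PTPN22, a phosphatase that restrains T cell receptor signalling (-2.82 and -2.85), fell in both. So did RXFP1 (-2.63 and -3.87), ANKRD35 (-6.63 and -2.60) and ATP1B2 (-4.43 and -2.43). With normexp background correction LRRC8C (0.83) and ATP1B2 (-0.94) were under 2-fold in MJ.

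Among 12179 genes well above background on all 4 arrays, 138 rose in both lines, against 41.5 expected of independent lists, and 116 fell in both, against 30.4 expected. Together these 254 genes compare with 71.8 expected. Another 109 genes went opposite ways by at least 2-fold, against 71.0 expected, 41 of them higher in MyLa and lower in MJ and 68 the reverse. Across genes, which are not independent replicates, the log2 differences of the lines were weakly related (Pearson's r 0.16, Spearman's correlation 0.17), and 54.9% had the same sign. With the lines as replicates and the line as a block, limma passed 0 of 14504 genes at an adjusted p of 0.05, with 800 at an unadjusted p under 0.05 where 725.20 are expected by chance. The fit has 1 residual degree of freedom, and on simulated data with the spread of these arrays it passed 0 of 50 genes changed by log2 6. IFNG had the smallest p in that limma fit, with a mean difference of 6.84 (SE 0.28) in the same direction in both lines and an adjusted p of 0.75. FABP6 followed at -4.82, with the same adjusted p.

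**Figure D2:**
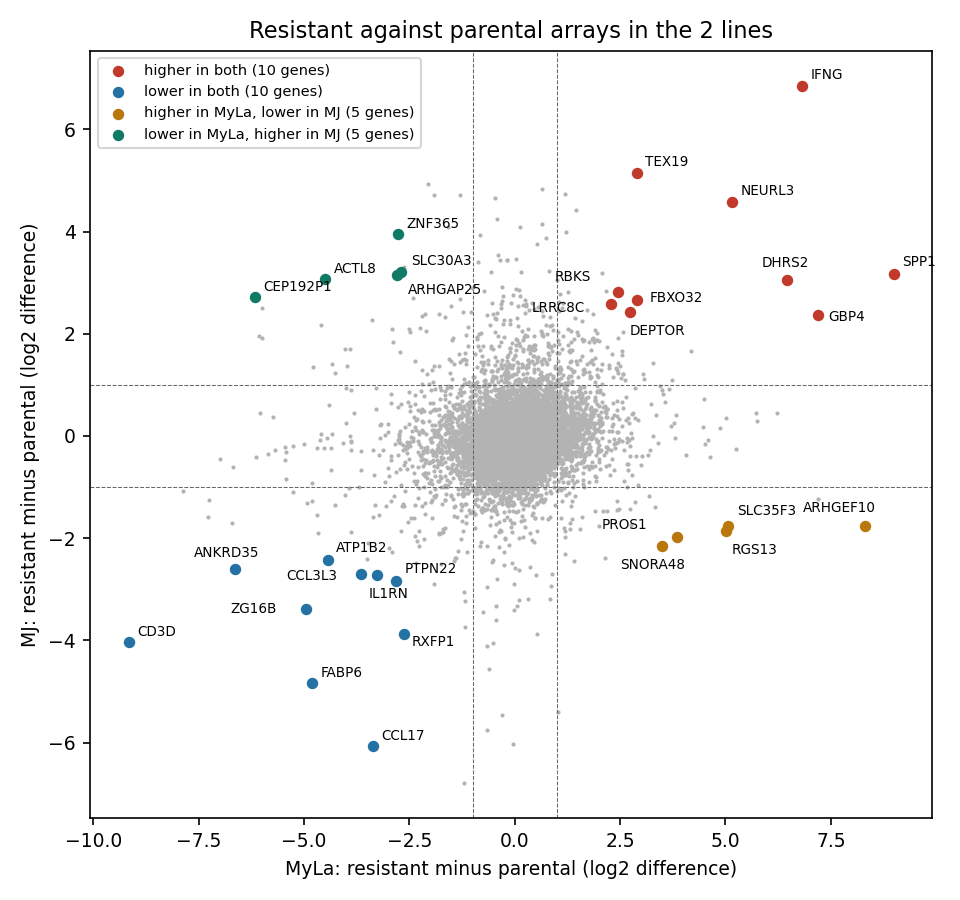
Log2 difference, resistant minus parental, in MyLa (x axis) and MJ (y axis) for genes well above background on all 4 arrays, with dashed lines at 2-fold. Grey points are single genes and coloured points are the named genes that rose in both lines, fell in both or went opposite ways. IFNG lies at 6.82 and 6.86, and CD3D at -9.16 and -4.04.

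**Figure D3:**
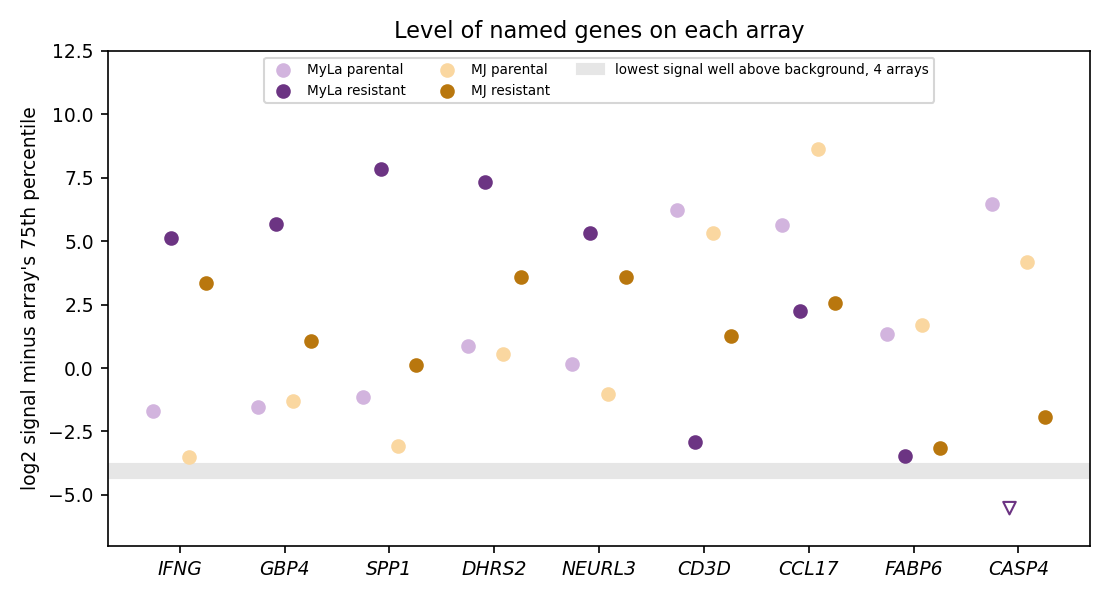
Log2 signal minus the array's 75th percentile (y axis) of 9 named genes on each of the 4 arrays, 1 point per array, with open triangles for signals not well above background and a grey band for the lowest signals that were. IFNG, GBP4, SPP1, DHRS2 and NEURL3 lie higher on both resistant arrays, and CD3D, CCL17, FABP6 and CASP4 lie lower.

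The parental lines were compared for context, as MyLa minus MJ. Parental MyLa carried far more CYP1B1, a cytochrome P450 gene (log2 9.82), TPM2, a tropomyosin gene (8.95), PNMA5 (8.37), the interferon-induced GTPase MX2 (8.03) and OOEP (7.94). Parental MJ carried far more of the immediate early gene EGR1 (-9.62), the homeobox gene OTP (-8.81), RCN1 (-8.12), the histone gene H2AJ (-8.03) and NREP (-7.85). Of 12471 genes measured on both parental arrays, 1391 were at least 2-fold higher in MyLa and 1704 in MJ, more than changed with resistance within either line. The arrays of a line resembled each other more (r 0.949 across genes for MyLa and 0.975 for MJ) than the parental arrays did (0.909). T cell fate transcription factors (median -1.13, percentile 0) and p53 targets (-0.78, percentile 0.02) were lower in parental MyLa than in parental MJ. NRF2 targets were called higher by their median (0.41, percentile 99.8), although 4 of 22 were at least 2-fold lower and 2 higher and their mean was -0.98. With resistance in MyLa these lists were called the opposite way (0.53, 0.76 and -0.24). The same parental MyLa array enters both comparisons with opposite sign, so an error on it alone would give this mirror image. Other lists were called too, such as cancer-testis antigens (percentile 99.97) and, by its median, MHC class II presentation (percentile 100), both higher in MyLa. Of 13 MHC class II genes, 5 were at least 2-fold lower there.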

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

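The comparison of opposite changes was planned, and no other test is reported here. Of the named genes, 26 differed by at least 2-fold in opposite directions in MyLa and MJ, 13 of them higher in resistant MyLa and lower in resistant MJ and 13 the reverse. Each line gives 1 value, so the difference between the lines was not tested. Values are log2 differences, resistant minus parental, for MyLa and then MJ. Higher in MyLa and lower in MJ were ARHGEF10 (8.31 and -1.77), SPOCK2 (7.19 and -1.23 on the brighter of its probes, but -0.18 and -0.49 on the other), SLC35F3 (5.07 and -1.76), RGS13 (5.01 and -1.87), PROS1, the gene of the anticoagulant protein S (3.85 and -1.98), and the small nucleolar RNA gene SNORA48 (3.50 and -2.16). The bounds for BNIP3, ENPP2 and PTPRR in MyLa were 7.86, 7.39 and 7.37, with -1.01, -2.18 and -2.33 in MJ. ACOT12 had a bound of 1.18 in MyLa and -5.01 in MJ, and ADGRL2 had 1.20 in MyLa and a bound of -6.48 in MJ. GPR65 gave 1.02 and -5.40, and PTPRC, the pan-leukocyte phosphatase CD45, gave 1.09 and -1.60, with its probes from 0.59 to 1.47 in MyLa.

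Lower in MyLa and higher in MJ were CEP192P1 (-6.16 and 2.72), ACTL8 (-4.50 and 3.07), ARHGAP25 (-2.79 and 3.15), ZNF365 (-2.76 and 3.95), the zinc transporter SLC30A3 (-2.71 and 3.21), the T cell kinase FYN (-2.09 and 1.21), STEAP1B (-2.06 and 4.93) and PTPRU (-1.92 and 4.72). The ATF4 targets CTH (-1.79 and 2.39) and CHAC1 (-1.16 and 1.97) belong here as well, as do AUTS2 (-1.30 and 4.71), the MAPK inhibitor gene SPRED1 (-1.50 and a bound of 1.39) and INPP4B (a bound of -1.50 and 1.26). Another AUTS2 probe gave 0.68 in MyLa, where it was well above background on only 1 array, and -0.37 in MJ. The list of NF-kB targets was called lower in MyLa (median -0.41) and higher in MJ (median 0.12), although more of its members fell than rose in MJ.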

How the results depend on the processing

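The alternatives were planned except the 75th percentile over detected probes and the use of median spot signal in normexp, which were chosen after the data were seen. Signal over background limits these results, since 43.0% to 46.9% of probes were well above background and a gene dim on 1 array has only a bound. Among the 29 list calls in the 2 lines, 29 held with all spots kept, 28 with the deposited value table and with the mean over a gene's probes, 27 with normexp, 26 with quantile normalization, 24 without a filter on dim genes and 18 by the list's mean. Median and detected-probe scaling add 1 constant per array, which moves a list and its random lists alike, so that all calls held under them shows nothing. Of 60 pairs of list and line not called, 18 gained a call under at least 1 alternative, most often MHC class I presentation in MJ (5 alternatives). Quantile normalization gave 2 such calls, normexp 3, genes well above background on all 4 arrays 6, no filter on dim genes 5, the mean over probes 6, the list's mean 6, members well above background on both arrays 3 and unmatched random lists 2. The interferon-stimulated genes were called higher in both lines under all 12 alternatives for lists, including the scalings that could not end the call. Their list shifts ran from 0.61 to 1.27 in MyLa, where 1.27 is the list's mean, and from 0.32 to 0.90 in MJ. The correlation between the lines stayed between 0.12 and 0.17. Of 363 named differences of at least 2-fold, 356 kept sign and size with quantile normalization and 289 with normexp. With normexp the log2 size of those 363 differences changed by a median of -24.4%. The shared change stayed at 0 genes in limma with no replicate block or pairing (202 at an unadjusted p under 0.05). It did so too under every other alternative that kept all 4 arrays (smallest adjusted p from 0.0617 to 0.824). On simulated data with the spread of these arrays, limma passed 0 of 50 genes changed by log2 6. A count of 0 therefore cannot tell whether the shared change depends on the processing. Each fit with an array left out had 1 array in a group and no pairing by line, so its count is not given. Slide row as a block was not run, since there is 1 slide. All-gene medians moved by less than 0.1 under every scaling.

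Normexp, whose added offset pulls dim signals together by construction, counted 1408 genes in MyLa and 729 in MJ, bounds for 235 and 84, parental bounds for 868, and 132 shared and 58 opposite genes. It kept 60.5% of the MyLa genes and 55.9% of the MJ genes. With it T cell receptor genes in MJ (-0.17), T cell fate factors in MyLa (0.22) and NK markers in MyLa (-0.35) lost their calls, and TET3 in MJ turned to -0.0069. Quantile normalization ended the calls on T cell receptor genes (-0.18) and ribosomal proteins (-0.023) in MJ and on autophagy in MyLa (0.33), and the value table the call on NRF2 targets in MyLa (-0.24). Genes well above background on all 4 arrays, a smaller set, ended those on fate factors (0.020 in MyLa, 0.044 in MJ), cytotoxic genes (-0.66 and -0.30), and cytokines (-0.27) and glycolysis (-0.31) in MJ. No filter on dim genes, which adds genes near background, gave 4134 genes in MyLa, 3041 in MJ, 6091 between the parental lines, 666 shared and 390 opposite. It ended the calls on drug conjugation (-0.29) and inhibitory receptors (-0.46) in MJ and on fate factors (0.31), cytokines (-0.23), cytotoxic genes (-0.30) and NK markers (-0.24) in MyLa. The mean over probes ended those on cytokines (-0.23) and NK markers (0) in MyLa, and turned MBP in MJ to -0.17, the mean of probes at 4.83, -3.56 and -1.80, the last dim on the resistant array. By construction, 1.5-fold gave 4703 genes in MyLa, 3051 in MJ (634 bounds), 5618 parental, 798 shared and 381 opposite, and 3-fold 936, 537 (240 bounds), 1523, 71 and 36. By the list's mean the calls ended for NRF2 targets (0.0037), fatty acids (0.00043), fate factors (0.20), cytokines (-0.11), cytotoxic genes (-0.58), glycolysis (-0.16) and autophagy (0.43) in MyLa and for NF-kB (-0.30), inhibitory receptors (-0.22), fate factors (0.21) and glycolysis (-0.26) in MJ. Only members well above background on both arrays ended those on fate factors (0.063) and cytotoxic genes (-0.66) in MyLa, and unmatched random lists those on NRF2 targets (-0.24) and autophagy (0.37) in MyLa and NF-kB (0.12) in MJ. Where no construction is named, the cause was not tested.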

Other observations

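All tests here were chosen after the patterns they weigh were seen. For the metallothionein neighbours, and for the brightness trend on chromosome 8 in MyLa and the chromosome 16 block in MJ, the predictions were written before those tests were run. Neighbouring genes shifted together along several autosomes. Values of chromosomes, blocks and windows are relative to the median difference of the line, while those of single genes are not. In resistant MyLa, 79.7% of the 429 measured genes of chromosome 8 were above that median, with a median of 0.63, which covers TP53INP1 (3.23), RRM2B (2.17) and the break repair gene NBN (1.82). Chromosome 13 had a median of -0.50 and chromosome 20 of 0.39. A block of 80 genes on chromosome 11 from ENDOD1 to CENATAC had a median of -0.66 and holds ATM (-2.50) and CD3D (-9.16). In resistant MJ, a block of 220 genes on chromosome 16 from POLR3K to MOSMO had a median of -0.79, with 91.8% of its genes lower, among them the acetyltransferase gene CREBBP (-0.85) and TSC2 (-1.22, and -0.63 on another probe), and a block of 163 genes on chromosome 5 from YIPF5 to TRIM52-AS1 had a median of -0.41. CREBBP also lay in a lower block of 77 genes in MyLa, from SRRM2 to ERCC4, which had a median of -0.60. Together, 9 blocks in MyLa held 6.65% of the genes and 12.2% of those past 2-fold, and 6 blocks in MJ held 4.42% and 9.27%. The blocks were chosen by their shift in these same differences, so a larger share past 2-fold follows in part from that choice. With quantile normalization there were 10 blocks in MyLa and 5 in MJ. The block at the start of chromosome 16 in MJ then held 219 genes, and the chromosome 5 block that ends at TRIM52-AS1 held 115.

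Blocks were merged from windows outside the range of the permuted gene orders, so each block exceeds that range by construction. The permuted orders weigh only whether any window leaves the range. Chance order of the genes does not account for such windows. The lowest window of 40 genes was -1.34 in MyLa and -0.94 in MJ, against -0.60 and -0.39 as the lowest over 1000 permuted orders. The highest was 0.87 in MyLa against 0.67, but in MJ it stayed inside the range (0.43 against 0.47). A trend of the difference with brightness does not account for the blocks either. The medians of 20 brightness bins spanned 0.15 in MyLa and 0.29 in MJ, and after they were removed all 15 blocks kept their sign with medians of at least 0.376 in size, the median of chromosome 8 in MyLa being 0.62 and that of the chromosome 16 block in MJ -0.79. A change in gene copy number may underlie the chromosome 16 block, where 91.8% of genes were lower, but expression alone cannot show DNA copies, and silencing of a region or outgrowth of a subclone remain open.

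The rise of IFNG and of interferon-stimulated genes on both resistant arrays is a further pattern. Scaling or brightness of the arrays is argued against as the whole cause, since under quantile normalization, which removed the shift of the ribosomal protein list in MJ, the list median lay at least 0.84 above that of random lists in both lines (0.85 against 0.0037 in MJ). Admixed cytotoxic T cells or NK cells are argued against, since 0 of 9 granule genes rose on either resistant array and 3 fell in each line. On both resistant arrays 5 of the 9, such as NKG7 and GNLY, were not well above background. The NK cell receptor genes KLRD1 (at least 18.7-fold) and KLRF1 (at least 8.42-fold) did rise in MyLa, and the cause of that was not tested. Admixture of the other parental line is argued against, since IFNG on the dimmer resistant array lay 5.03 log2 units above the brighter parental array. A response of the cells to their own interferon gamma may contribute: 5 of 10 genes known to respond (such as IRF1, GBP1, GBP4 and CXCL9) rose in both lines, but CXCL10 fell in MyLa (-2.92) while it rose in MJ (2.09), GBP5 rose in MyLa (4.87) but not in MJ (0.15), and SOCS1 (0.27 and -1.19) and CIITA (-0.06 and -0.57) rose in neither, so this stays open, as does an effect of resistance itself, which was not tested.

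Of 7 measured metallothioneins of chromosome 16, 5 fell in resistant MyLa. The explanation by zinc and what it predicts were reworded after the value of SLC30A1 was seen: as first worded, with a weaker zinc sensor included, it had been argued against by that rise. Loss of a segment that reaches the neighbouring genes is argued against, since the 20 nearest measured genes had a median of -0.077 (quartiles -0.36 and 0.32), 3 of them at least 2-fold lower. These genes lie outside the cluster, so they cannot decide on a smaller loss within it, which stays open. Less zinc in the cells could lower them, and the zinc exporter gene SLC30A1, which the same zinc sensor drives, was higher by 2.23. That speaks against a weaker sensor, but more export would itself lower zinc, so this stays open. Probes of similar family members may read 1 transcript, since 4 of the 5 fallen members lay within 1 log2 unit of their median, so these members cannot be told apart. Whether resistance itself, or vorinostat if it was present in the culture, lowered them was not tested.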
